A study of Glycine soja with 2 samples.

How the data were processed

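The data are 2 single-cell RNA libraries of wild soybean seed, made per the labels with the 10x Chromium 3' version 3 chemistry, in which polyadenylated RNA of single cells is tagged with a cell barcode and a UMI in droplets. The authors deposited, for each library, a sparse matrix of UMI counts per gene and barcode with its lists of genes and barcodes. Cell Ranger 5.0.0 made the matrices, per the file headers, and the submitters' processing notes name Cell Ranger and the aligner STAR without a version. The genome build, the annotation and the way cells were called are not given in the sources used here. The lowest barcode total was 500 UMIs in both libraries. The values were whole numbers, with totals that differed between barcodes, and were used as raw counts.

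Everything that follows was computed from the deposited counts. Cells were kept with at least 1000 UMIs and at least 500 genes, which left 12969 cells in library 1 (3091 barcodes had fewer than 1000 UMIs) and 11273 in library 2 (2182 barcodes). No filter on organelle transcripts was applied, because no identifier could be matched to a gene name. Doublets were scored with the scrublet method in scanpy 1.11.5, which called 1 barcode in each library, or 0.00771% and 0.00887% of cells. A caller that marks under 0.5% was taken not to have worked, and by the rule fixed for that case the highest-scoring 5% of barcodes were removed. This took out 625 cells (4.82%) and 534 cells (4.74%), without a check that these were doublets. Counts were scaled to 10000 per cell and logged, 3000 variable genes were chosen within libraries and scaled within each library, and 30 principal components, 20 neighbours and Leiden clustering at resolution 0.6 were used with a fixed seed (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). Clusters 14 and 19 had fewer than 50 cells in at least 1 library and stayed out of the tests. The leading feature of a cluster is the clustering feature with the largest fold of its lower library over the mean of the other clusters, with 5 CPM added to both.

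Cells are not replicates, so counts were summed per library and cluster. The sums were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, the filterByExpr filter, which left 22517 genes, and the quasi-likelihood test with the library as a block. Each cluster was set against the mean of the other 16 in a single fit with 16 residual degrees of freedom. The spread of each gene was shrunk towards that shared by other genes, with a median of 221.9 prior degrees of freedom. The p-values of most genes thus rest more on spread pooled over genes than on the gene's own spread between the libraries. The block stands for the shared cell suspension of a library and for nothing else, as there is 1 group. Calls needed a Benjamini-Hochberg adjusted p under 0.05 within a cluster comparison and at least 2-fold. Genes used as clustering features, 1526 of those left by the filter, were not counted, but the clusters were built from the same cells, so the p-values are too small for any gene that varies together with those features. The common biological coefficient of variation was 0.0633. On simulated counts for the real genes, 50 genes of at least 10 CPM were changed by each of 4 folds in cluster 5, among 19302 genes. The test at an adjusted p under 0.05 recovered 100% of genes raised 2-fold and 100% raised 4-fold. It recovered 98% of those lowered to 0.5 of their level and 100% lowered to 0.25. Of 217 calls there 18 were false. The sums of cluster 5 held 4688906 and 5080124 UMIs, and recovery of weaker genes or in smaller clusters was not simulated.

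Levels are CPM over the sum of a cluster in a library, with their mean and SD over the 2 libraries. Correlations of summed profiles between the libraries used log2 of CPM with 1 CPM added. Correlations between clusters, and those that matched clusters made in each library alone, added 5 CPM and used genes of at least 5 CPM. The correlations between clusters also left out the clustering features. Fold changes in a library alone used log2 CPM with a prior count of 2. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. Intervals and floors cover counting error only. The depth behind a cluster in a library is between 52 cells (cluster 18, library 2) and 1838 cells (cluster 1, library 1) among the clusters tested.

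Before the data were examined, 17 gene lists (storage proteins, oil and sugar metabolism and others) and 10 lists of cell type markers had been fixed as patterns on gene product names. The gene table used for names, of assembly ASM419377v2, holds none of the file's identifiers, so these lists were not tested. The rule for named genes was, without names, the 2 largest rises and 2 largest falls over all clusters among genes of at least 10 CPM outside the features, past the test and changed the same way in both libraries. The leading features and the 4 most abundant transcripts were named in addition, after their values were seen. The alternatives tried were other depth filters, doublets kept, other resolutions and scaling of features, DESeq2 1.42.0 and its size factors, no expression filter, no library block, subtraction of 10% ambient profile (the summed counts of all kept cells of the library, as free RNA was not measured), features included, and each library left out. Others were added after seeing the data: cluster 14 left out, cluster 2 left out, clusters 14 and 19 included, adjustment over all clusters together, and all barcodes for the shares of UMIs of the 4 abundant transcripts. Figures were drawn with matplotlib 3.10.9.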

Results

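Seed cells of wild soybean (Glycine soja), the wild relative of cultivated soybean, were profiled by droplet single-cell RNA sequencing. The 2 samples carry the name ZYD, the tissue label seed and a number each, and no label tells them apart by condition, stage or plant. They were therefore treated as 2 libraries of 1 group, and no comparison between conditions was made. The series as a whole concerns how seeds of wild soybean accumulate nutrients while they develop, and the single-cell part asks which cell populations a seed holds and how their transcripts differ. The deposited matrices held 67155500 UMIs (unique molecular identifiers, each standing for 1 captured transcript) over 16060 barcodes in library 1, and 63990798 UMIs over 13455 barcodes in library 2. After filtering, 12344 cells with a median of 3676 UMIs and 1629 genes were kept in library 1, and 10739 cells with a median of 4227 UMIs and 1762 genes in library 2.

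Transcripts are given by the gene identifiers of the files, which the files do not pair with gene names. None of the 55539 identifiers matched the gene table used here (0 matches), so clusters are described by number, and no cell type or pathway was assigned. Of these identifiers, 14224 had no UMI in any barcode.

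The first question was how closely the libraries repeat each other. Across 40922 genes with a UMI in the kept cells, the summed profiles of the libraries correlated with Pearson's r = 0.998 and Spearman's rho = 0.991. These are correlations across genes, and genes are not independent replicates. Of 9076 genes with a mean of at least 10 CPM (a gene's count relative to the total of its sum), 0 differed more than 2-fold between the libraries, and the median difference was 1.06-fold. The libraries still differed by more than the counting noise of UMIs, with a chi-square of 10.6 per degree of freedom over 30676 genes, which does not show that they are separate samples. They shared 66 barcodes, of which 41 were kept in both, and 3 of these fell in the same cluster against 3.82 expected by chance. The edgeR tests below rest on how far clusters vary between these 2 libraries, mostly as pooled over genes. Nothing in the labels says that the libraries came from separate plants, so this may be technical variation.

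The kept cells formed 19 clusters, numbered by size, and the makeup of the libraries was close apart from cluster 14. Cluster 1 held 14.9% of cells in library 1 and 15.4% in library 2, cluster 2 held 13.9% and 14.9%, and cluster 3 held 11.4% and 13.6%. Clusters 4, 5 and 6 held 9.41% ± 0.87, 8.76% ± 0.26 and 8.45% ± 0.045 of cells (mean ± SD, n = 2). The other clusters held from 5.16% ± 0.53 in cluster 7 to 0.315% ± 0.068 in cluster 19. The exact binomial 95% intervals of the shares overlapped between the libraries in 16 clusters and lay apart in 3, and these intervals cover counting error only. The intervals of cluster 3 were 10.9% to 12.01% in library 1 and 12.96% to 14.3% in library 2, and those of cluster 4 were 8.30% to 9.31% and 9.47% to 10.6%. Cluster 14 held 430 cells of library 1 (3.48%, interval 3.17% to 3.82%) and 7 cells of library 2 (0.0652%, interval 0.0262% to 0.134%). With doublets kept it held 524 cells of library 1 (4.04%) and 57 of library 2 (0.506%), of which 88 and 45 had been removed for their doublet score. It then had enough cells to be tested, with 2132 calls. Outside cluster 14 the shares of the libraries differed by at most 1.48-fold. The division among the large clusters depended on the settings: 14 clusters formed at resolution 0.3 and 27 at resolution 1.2. Cluster 5 held 2.63% of cells with features scaled over both libraries together, when 857 of its cells joined cluster 1 and 525 joined cluster 4, and 3.16% with doublets kept, when cluster 4 held 16.9%. When cells of at least 2000 UMIs were thinned to that number and clustered again, 0% of the 1597 cells of cluster 2 and 36.4% of the 3087 cells of cluster 1 sat in a cluster in which they were the majority. Without thinning, clustering the cells of at least 2000 UMIs left 1288 of the cells of cluster 2 together, as 79.5% of the cells then named cluster 2. Cluster 2 thus formed no cluster of its own at equal depth, and whether depth sets it apart or thinning removed too many UMIs to tell was not tested. The share was 59.8% in cluster 5 and 63.9% in cluster 19, and 75.8% to 98.7% in the other clusters.

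**Figure D1:**
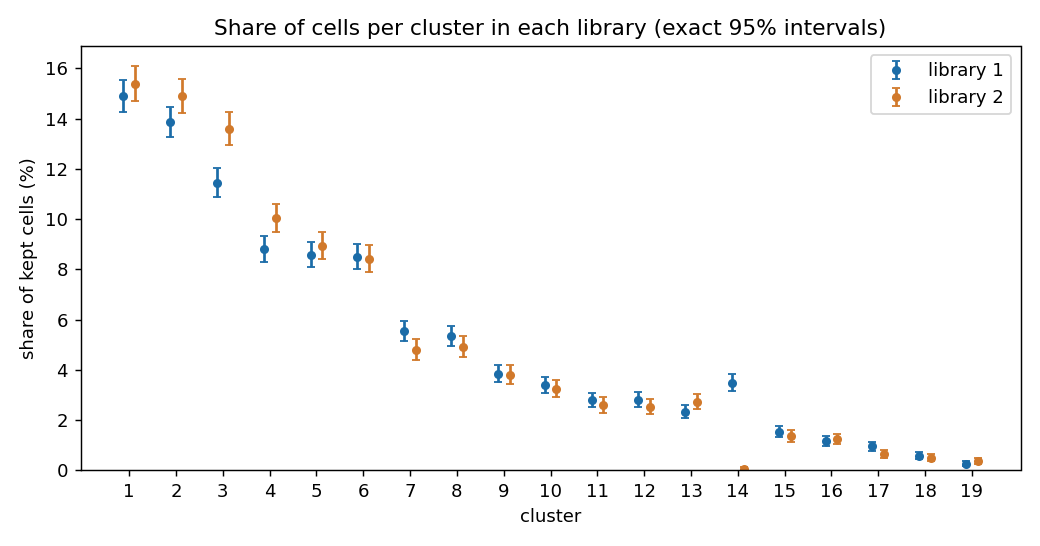
Share of kept cells (%) in each of the 19 clusters, for library 1 and library 2; points are shares and bars are exact 95% binomial intervals, which cover counting error only. The libraries lie close together in most clusters, while cluster 14 holds 3.48% of library 1 and 0.0652% of library 2.

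Each cluster was marked by transcripts among the features used for clustering, which define it and are no independent finding. In cluster 18 Glysoja.01G001780 reached 1847 CPM ± 492 (SD, n = 2), 1200-fold above the mean of the other clusters, and in cluster 16 Glysoja.08G022511 reached 1160 CPM ± 31, 366-fold above them. Cluster 12 was led by Glysoja.03G006036, at 6506 CPM ± 251 and 203-fold, and cluster 8 by Glysoja.18G049193, at 588 CPM ± 20 and 183-fold. Cluster 17 was led by Glysoja.15G040118 at 116-fold, cluster 9 by Glysoja.12G035128 at 75.9-fold, cluster 10 by Glysoja.06G015165 at 58.2-fold and cluster 7 by Glysoja.18G047121 at 21.4-fold. Glysoja.09G023521 led cluster 6 at 17.2-fold, Glysoja.17G045351 led cluster 15 at 15.0-fold, Glysoja.01G000206 led cluster 4 at 11.7-fold, Glysoja.07G016585 led cluster 13 at 10.7-fold and Glysoja.07G018396 led cluster 11 at 8.24-fold. Leading features of the remaining tested clusters stood out less: Glysoja.18G049928 led cluster 3 at 6.80-fold, Glysoja.11G030593 cluster 5 at 5.04-fold, Glysoja.12G034697 cluster 2 at 4.95-fold and Glysoja.03G006516 cluster 1 at 4.39-fold. Cluster 14 was marked least of all 19 clusters, with a leading fold of 2.98 (Glysoja.04G008630). Both this value and the choice of the feature rest partly on its 7 cells in library 2. The number of features more than 2-fold above the mean of the other clusters in both libraries ranged from 8 in cluster 5 to 452 in cluster 8 among the clusters tested below.

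The clusters also differed in depth and in how evenly their UMIs spread over genes. Cells of cluster 2 were the shallowest, with medians of 1874 UMIs in library 1 and 2034 in library 2, and cells of cluster 14 the deepest in library 1, with a median of 13114 UMIs. With every cell thinned to 1000 UMIs, the minimum for a kept cell, cells of cluster 17 showed the most genes, with medians of 705 and 701, while cells of clusters 2, 3, 5 and 13 showed medians of 574, 563, 572 and 565 in library 1 and 554, 549, 552 and 545 in library 2. Without thinning, the medians of cluster 17 were 1311 and 1595 genes and those of cluster 3 were 2118 and 2221. The 10 most abundant genes of a cluster took 32.8% of the UMIs of cluster 2 in library 2 but 7.65% of those of cluster 17.

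The profiles of the clusters were compared pair by pair. Over 13652 genes outside the clustering features the most similar pair was clusters 1 and 2 (r = 0.971 across genes). Cluster 3 was nearest to cluster 1 (r = 0.960). Clusters 4 and 9 correlated at r = 0.959, clusters 5 and 9 at r = 0.944 and clusters 5 and 10 at r = 0.939. Clusters 6 and 7 correlated at r = 0.944, and cluster 12 was nearest to cluster 7 (r = 0.913). The pair farthest apart was clusters 2 and 6, at r = 0.628. Between the libraries, the profile of the same cluster correlated at r = 0.876 to 0.994 over the 17 clusters with at least 50 cells in each library. These values run over all identifiers, also those without a UMI, so they are not on 1 scale with the values between clusters. When each library was clustered alone, it gave 19 and 16 clusters, of which 15 pairs were each other's best match. Their median r was 0.881 and the lowest 0.415, across genes with a mean of at least 5 CPM. For these values each gene was centred on its mean over the clusters of its library. Cells were not all grouped as in the joint clustering. The adjusted Rand index, the agreement of 2 groupings of cells beyond chance, was 0.653 in library 1 and 0.673 in library 2.

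**Figure D2:**
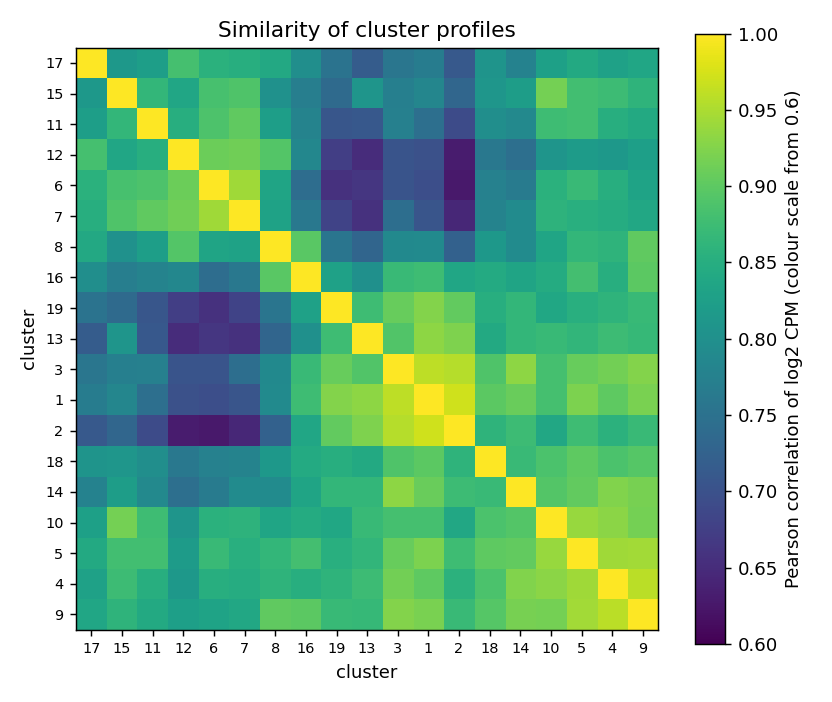
Pearson correlation across genes of the log2 CPM profiles of the 19 clusters, both axes giving the cluster number in the order of average-linkage clustering; the colour scale starts at 0.6. Clusters 1 and 2 form the most similar pair (r = 0.971) and clusters 2 and 6 the least similar (r = 0.628).

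A few transcripts dominated the seed cells, and their shares differed between clusters. The 4 identifiers with the most UMIs, named after their values were seen, took 16.1% of all UMIs in library 1 and 18.0% in library 2, and none was a clustering feature. Glysoja.03G007349 alone took 8.42% ± 0.83 of UMIs (SD, n = 2). Its share was highest in cluster 2, at 12.7% ± 0.55, and lowest in cluster 12, at 1.43% ± 0.095, and it passed the test described next as higher in clusters 1, 2, 3, 4, 5 and 13 and as lower in clusters 6, 8, 12, 15 and 17. Its log2 fold change was 1.63 (SE 0.116) in cluster 5, with an edgeR quasi-likelihood adjusted p of 2.47e-09, and -2.10 (SE 0.168) in cluster 12, with an adjusted p of 1.23e-08. Glysoja.11G032100 took 3.15% ± 0.13 of UMIs and differed from the first in where it peaked: its share was 5.65% ± 0.31 in cluster 11, 5.19% ± 0.40 in cluster 5 and 5.13% ± 0.13 in cluster 3, and it was called higher in these 3 clusters only. In cluster 11 its log2 fold change was 1.94 (SE 0.098, adjusted p of 8.1e-12, edgeR). Glysoja.08G022501 took 3.02% ± 0.0074 of UMIs and showed the widest range, from 5.78% ± 0.047 in cluster 3 to 0.381% ± 0.079 in cluster 6, a ratio of 15.2. It was called higher in clusters 1, 2, 3, 4 and 13, with a log2 fold change of 2.75 (SE 0.167, adjusted p of 7.07e-11, edgeR) in cluster 3, and lower in 7 clusters. In cluster 11, where Glysoja.11G032100 peaked, its share was 0.530% ± 0.084. Glysoja.10G028044 took 2.45% ± 0.39 of UMIs, with 4.61% ± 0.35 in cluster 2 and 0.517% ± 0.0084 in cluster 7. It was higher in clusters 1, 2, 3, 5 and 13 and lower in clusters 6, 7, 8, 12 and 17. In cluster 17 the log2 fold changes of Glysoja.08G022501 and Glysoja.10G028044, -2.34 and -1.95, became -0.07 (SE 0.237) and -0.39 (SE 0.115) and were no longer called when cells needed at least 2000 UMIs, where cells of clusters 17 and 19 formed 1 cluster. The sizes of the fold changes also moved under other settings. The ambient profile was the sum of all kept cells of a library and not measured free RNA. Subtracting it tends by construction to enlarge a difference from the average cell. Keeping doublets moved cells between clusters and brought cluster 14 into the fit. For Glysoja.03G007349 in cluster 12 the log2 fold change was -2.999 with an ambient profile of 10% subtracted and -1.33 with doublets kept, and in cluster 5 it was 1.93 and 1.15. For Glysoja.11G032100 in cluster 11 it was 2.35 and 1.69. For Glysoja.08G022501 it was 3.52 and 2.37 in cluster 3 and -3.64 and -1.93 in cluster 17, and for Glysoja.10G028044 in cluster 17 it was -2.46 and -1.62. Barcodes under 1000 UMIs held Glysoja.03G007349 at 7.75% and 8.18% of their UMIs, against 7.84% and 9.01% in kept cells. These barcodes were not shown to be empty droplets, so their share cannot tell free RNA from expression. Its UMIs in the low clusters were not read as expression by their cells.

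**Figure D3:**
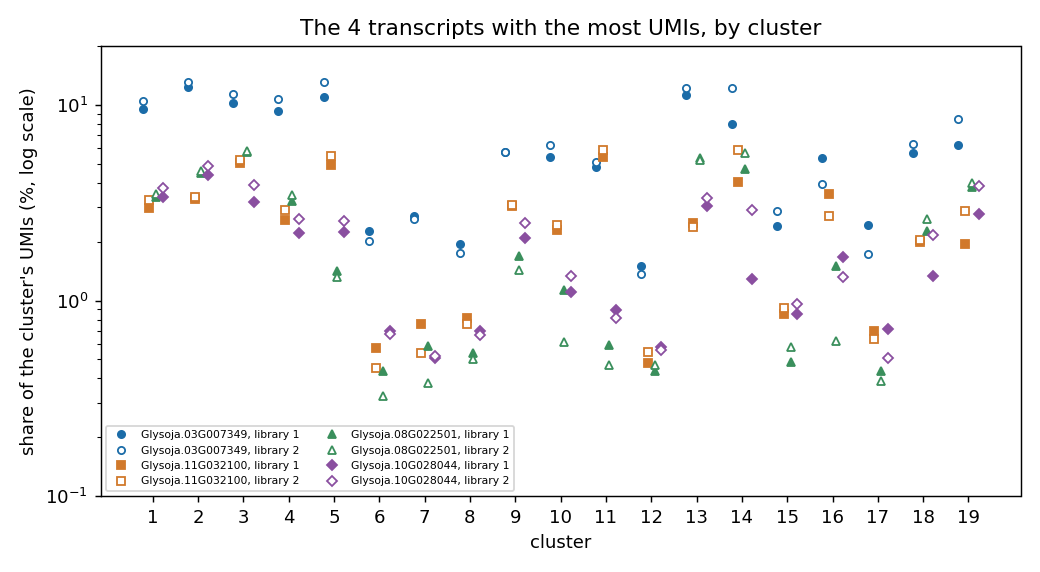
Share of a cluster's UMIs (%, log axis) taken by each of the 4 transcripts with the most UMIs, for each of the 19 clusters; filled symbols are library 1 and open symbols library 2. The share of Glysoja.03G007349 runs from 12.7% in cluster 2 to 1.43% in cluster 12, and Glysoja.08G022501 falls to 0.381% in cluster 6.

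To ask which genes differ between cell populations, counts were summed per library and cluster, and each of the 17 clusters was compared with the mean of the other 16. Outside the clustering features, 17263 of 20991 genes differed at least 2-fold at an adjusted p under 0.05 in at least 1 cluster. Cluster 6 had the most calls, with 3795 genes higher and 2725 lower, although without the expression filter cluster 2 had more (7909 against 7384). Cluster 2 followed with 3540 higher and 2429 lower, then cluster 7 with 3618 and 2312, and cluster 13 with 3558 and 2067. Cluster 2 was the shallowest cluster and formed no cluster of its own at equal depth, so its calls may not mark a separate population. Clusters 11 and 12 had 2858 and 2752 genes higher and 2272 and 2330 lower. Clusters 9 and 10 differed almost only upward, with 1674 and 2006 genes higher against 225 and 224 lower. All 17 clusters had more higher than lower calls, from 51.6% higher in cluster 17 to 90.0% in cluster 10. The comparison averages log levels over the other clusters, so a gene scarce in a few of them can be called higher in many others. How far this accounts for the excess was not tested. Cluster 4 had 2022 higher and 483 lower, and cluster 5 had 1381 higher and 336 lower. The smallest cluster tested, cluster 18, had 742 genes higher and 360 lower. Of 15384 genes higher in any cluster, 4448 (28.9%) were higher in a single cluster and 2404 (15.6%) in at least 5. The fold changes of all tested genes correlated between the libraries at r = 0.899 in cluster 3 and r = 0.285 in cluster 18, the extremes of the 17 clusters. In library 1 alone 3000 of the 4513 calls in cluster 1, 1482 of the 2505 in cluster 4 and 991 of the 1717 in cluster 5 were still at least 2-fold, and in library 2 alone 1620 of those in cluster 4. Cluster 4 had 1369 calls with doublets kept, and cluster 1 had 6935 without an expression filter. The sums of clusters 17 and 18 are the smallest of those tested, with 332800 and 266778 UMIs in cluster 17 and 276883 and 329906 in cluster 18.

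**Figure D4:**
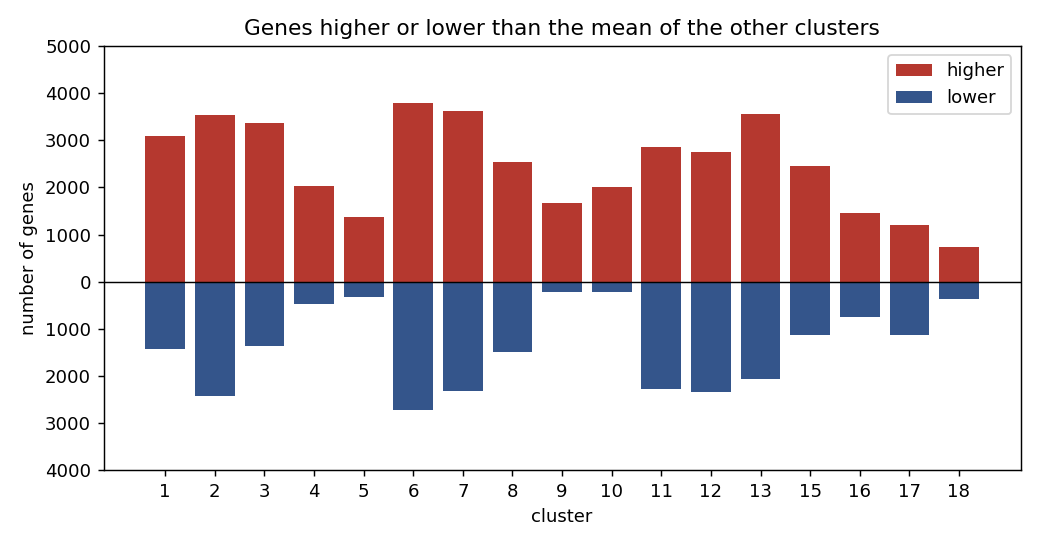
Number of genes higher (upward bars) and lower (downward bars) in each of the 17 tested clusters than in the mean of the others, by the edgeR quasi-likelihood test at an adjusted p under 0.05 and at least 2-fold. Cluster 6 has the most calls (3795 higher, 2725 lower) and cluster 18 the fewest (742 higher, 360 lower).

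The balance of higher and lower calls depended on the scaling and on other settings. With DESeq2 size factors in place of edgeR's TMM factors, the change of factors amounted to a shift of -0.17 on the log2 scale in cluster 6, of -0.12 in clusters 5 and 7, and of 0.16 in cluster 17, 0.12 in clusters 16 and 18 and 0.12 in cluster 13. The calls then became 2922 higher and 3388 lower in cluster 6, so that lower genes outnumbered higher ones. The same held in cluster 11, with 2440 higher and 2706 lower against 2858 and 2272 before, at a shift of -0.10. They became 968 and 495 in cluster 5, 1713 and 537 in cluster 16 (1462 and 752 before), 1538 and 821 in cluster 17 (1210 and 1135 before), and 851 and 230 in cluster 18. The DESeq2 test on the same sums gave 2737 higher and 4144 lower in cluster 6 and 2931 and 3466 in cluster 7. In cluster 11 it gave 2455 and 2223, on the same side as the main test. It also gave 2986 and 1940 in cluster 3 (3360 and 1375 before), 1471 and 730 in cluster 4, 786 and 574 in cluster 5, 2074 and 360 in cluster 16, 1995 and 620 in cluster 17, and 1102 and 126 in cluster 18. The clusters entering the fit mattered as well: with clusters 14 and 19 included, which was added after seeing the data, cluster 17 had 1840 higher and 796 lower, cluster 12 had 3995 and 1740, cluster 8 had 3459 and 1053, cluster 16 had 1709 and 484, and cluster 3 had 2184 and 1678.

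By the rule fixed beforehand, the 2 identifiers with the largest fitted rise over all clusters and the 2 with the largest fall are given. Both rises were in cluster 7. Glysoja.08G022686 stood at 72.7 CPM ± 1.8 there against a mean of 6.29 CPM in the other clusters, an 11.6-fold difference, and its highest level in another cluster was 38.8 CPM. Its fitted log2 fold change was 5.29 (SE 0.154), with an edgeR quasi-likelihood adjusted p of 6.27e-71. Glysoja.11G032331 stood at 109 CPM ± 4.5 against a mean of 15.0 CPM, a 7.29-fold difference, with 96.4 CPM in the next highest cluster, and its fitted log2 fold change was 5.24 (SE 0.115, adjusted p of 3.85e-115, edgeR). The fitted values average log levels over the other clusters, 1 of which held no UMI of either identifier, so they depend on the prior count and exceed the ratio of the mean levels. With an ambient profile of 10% subtracted, which tends by construction to enlarge such differences, they were 6.39 and 7.04. In library 2 alone, with a larger prior count, they were 4.42 and 4.69. With doublets kept they were 4.97 and 4.62. Both falls were in cluster 17, which held 0 UMIs of either identifier in both libraries. Against the floor that 3 counts over both libraries allow, 5.004 CPM, Glysoja.16G042388 was at least 4.16-fold lower than its mean of 20.8 CPM in the other clusters (adjusted p of 3.9e-05, edgeR), and Glysoja.10G026800 at least 3.93-fold lower than its mean of 19.6 CPM (adjusted p of 6.54e-06, edgeR). With at least 2000 UMIs per cell, where the cluster also took in cells of cluster 19, the fall of Glysoja.16G042388 was -1.13 (SE 0.431) on the log2 scale and no longer called. That of Glysoja.10G026800 shrank to -0.82 (SE 0.417), under 2-fold, and the gene became a clustering feature, which is not tested.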

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

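The test of droplets that hold several cells of any combination, the test of 1 source of free RNA, the look at barcodes under 1000 UMIs and the count of removed cells in cluster 14 were chosen after the result was seen.

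Cluster 14 is a signal outside the tests: 3.48% of the kept cells of library 1, with 10.3% of its UMIs, and 7 cells of library 2. With doublets kept it held 57 cells of library 2 (0.506%) and 524 of library 1 (4.04%). Of these, 45 and 88 had been removed for their doublet score. A gap between the libraries thus remained with doublets kept, but its size depends on that removal, which was not checked. Of all cells past the depth filter it had taken 4.74% in library 2 and 4.82% in library 1, so high doublet scores were over-represented here. Depth alone is argued against, because with every cell thinned to 2000 UMIs 78.9% of these cells still sat in a cluster in which they were the majority, and that cluster held 416 cells of library 1 and 9 of library 2. The same thinning left 0% of cluster 2 and 36.4% of cluster 1 in such a cluster. Of simulated pairs of library 1 cells that met at random, 2.35% landed near cluster 14. By the rule set beforehand this argues against random pairs of the depth simulated, a median of 7964 UMIs against 13114 in cluster 14. Of simulated droplets of 3 cells (median 12564 UMIs) 5.5% landed there, and of 4 cells 12.9%. The cells used had also lost those with the highest doublet scores, so droplets of deeper or more cells that met at random stay open. Droplets holding several cells in some other combination cannot be told apart from a separate population: 0 genes of at least 20 CPM stood more than 1.5-fold above every other cluster of library 1, but clusters 1 and 5 had only 2 and 3 such genes. The profile was met within 2-fold by a fitted mixture (mainly 54.2% cluster 3, 14.1% cluster 4, 10.4% cluster 7) for all but 68 of 4762 genes. No other cluster was fitted in this way, so the fit cannot tell a mixture from a separate population. Against a mixture, 13 of 952 genes present in every other cluster lay below 0.5 of the lowest of them, though clusters 2 and 13 had 18 and 12 such genes. All 13 were higher in the 629 cells of clusters 3 and 4 with at least 8960 UMIs (median 2.79-fold, lowest 1.87-fold). They had been picked as low against every other cluster, these 2 among them, and depth was cut at a minimum and not matched. The comparison therefore cannot decide whether depth accounts for their level. The 13 genes were also enriched in barcodes under 1000 UMIs (median 4.02-fold). Whether droplets of several cells would hold less of such transcripts was not tested, so these genes do not settle the question of a mixture. No biological explanation was tested, since the labels give no group that parts the libraries, and a population that differs in share between them stays open.

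Cluster 19, at a mean of 0.315% of cells, lies outside the tests for its size and was led by Glysoja.11G029813 at 385 CPM ± 133 (SD, n = 2).

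Barcodes under 1000 UMIs, which the main comparisons leave out, gave 1.51% of their UMIs in library 1 to Glysoja.U055302, 7.66-fold its share in kept cells, and 1.501% in library 2, 7.38-fold; 6 of 1302 genes of at least 100 CPM were over 3-fold enriched in such barcodes of both libraries.

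The most abundant transcript, Glysoja.03G007349, was low but never absent in clusters 6, 7, 8, 12, 15 and 17, which raises the question of free RNA. A single source with a fixed mix of transcripts as the whole cause is argued against, because the ratio of the second to the first most abundant transcript varied 1.64-fold between these clusters in library 1 and 2.09-fold in library 2. Free RNA as such stays open and cannot be told apart from expression. The count of the transcript in the deepest 1 in 4 cells was 2.03 to 6.12 times that in the shallowest 1 in 4, while depth itself rose 2.79 to 5.95 times, and the lowest values, 2.03 in cluster 8 of library 2 and 2.29 in cluster 12 of library 1, lie between what free RNA and what expression would give. No biological explanation was tested for this pattern.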

How the results depend on the processing

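The settings added after seeing the data are named as such. Lists of genes by function, and keeping them among the clustering features, were not run, as no identifier matched a gene name. Agreement of the libraries stayed at r = 0.998 with the deeper library thinned, with all barcodes (0.998487, just above the interval of the main value; the cause was not tested) and with cluster 14 left out (added). The number of clusters changed from 19 to between 14 and 27, all within 1.5-fold. Of 107 values for the share of a cluster under another setting, 61 lay within 1 SD. Besides clusters 4 and 5 with doublets kept (16.9% and 3.16%) and cluster 5 with features scaled over both libraries (2.63%), values over 1.5-fold from the main share were: at resolution 0.3, cluster 1 (35.9%), 3 (6.11%), 5 (16.8%) and 13 (4.12%), clusters 2, 4, 14, 15 and 19 having no cluster of their own there; from 500 UMIs, cluster 3 (8.03%), 13 (4.04%) and 17 (1.26%); from 2000 UMIs, cluster 2 (8.98%), 4 (14.3%) and 13 (4.86%); and with doublets kept, cluster 13 (4.02%).

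Of 250 gene counts over 14 other settings, 243 lay within 1.5-fold of the main count. Cluster 6 had the most calls in each of these settings except without an expression filter, where cluster 2 had 7909 and cluster 6 had 7384. The 7 other counts follow. Without an expression filter cluster 1 gave 6935 genes in place of 4513, among 37813 tested genes. With doublets kept, cluster 4 gave 1369 in place of 2505, where only 43.8% of its cells came from cluster 4 and 31.3% from cluster 5. Adjusted over all clusters together (added), cluster 18 gave 1690 in place of 1102, all tests sharing 1 threshold. Taking calls still 2-fold in 1 library alone, which allows no test, cluster 1 kept 3000 to 3392, cluster 4 kept 1482 to 1620 and cluster 5 kept 991 to 1151 (of 1717), and over all clusters 15824 to 16156 of 17263 genes stayed. Leaving out the library block, the only form of replicate block here, left 17263 genes called in any cluster. The split into higher and lower calls moved by over 10 points under settings other than scaling too. Without an expression filter it became 5648 higher and 1287 lower in cluster 1, 5606 and 2303 in cluster 2 and 5494 and 1183 in cluster 3. From 2000 UMIs it was 1137 and 542 in cluster 17 and 3250 and 1157 in cluster 13, and with doublets kept 1482 and 849 in cluster 5. No paired analysis between groups was possible because there is 1 group.

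All 164 fold changes of named genes under other settings kept their sign, though for part of them this was fixed beforehand. The settings with features included and with adjustment over all clusters together reuse the main fold changes. The named rises and falls had been chosen for the same sign in both libraries, and the abundant transcripts were placed in their most extreme clusters. Of 140 values with a test, 137 stayed past the threshold. The 3 exceptions (Glysoja.16G042388, Glysoja.08G022501 and Glysoja.10G028044) were falls in cluster 17 with at least 2000 UMIs (-1.13, -0.07 and -0.39, the second within its SE of 0), where 64.3% of its cells came from cluster 17 and 32.2% from cluster 19. Glysoja.10G026800, a clustering feature there and so not among these values, also shrank, to -0.82 (SE 0.417) in cluster 17. Depth and the change of cells were not tested apart.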

Other observations

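The test of whether neighbouring identifiers share a cluster was chosen after the result was seen; its repeat without clusters 12 and 16 was set before that value was known.

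Genes that stand next to each other in the deposited list peaked in the same cluster more often than shuffled genes. Pairs of a numbered identifier and a U identifier were left out, but pairs that span 2 chromosome numbers were not. Of 5092 adjacent pairs in which both genes were higher in some cluster, 552 (10.8%) had the same highest cluster, against a mean of 7.63% and a highest value of 9.05% over 10000 shuffles of the clusters over the genes (p = 0.0001, permutation, one-sided, the smallest these shuffles can give). Without the genes highest in clusters 12 and 16, the share was 12.6% against a mean of 8.91% and a highest value of 10.9%, so those 2 strongly marked clusters alone do not account for it. The share fell with distance in the list, to 9.28% for genes 2 places apart, above the highest of 1000 shuffles (8.65%, p = 0.001, permutation), and 8.72% at 5 places (p = 0.007, permutation, 1000 shuffles). At 10 and at 50 places it was 7.66% (p = 0.5 at each, permutation, 1000 shuffles). A candidate explanation is that neighbours on a chromosome are expressed together. Reads shared between near-identical copies that lie side by side could give the same pattern, and this was not tested, as no sequence was used here; nor was it tested that the order of the identifiers follows the chromosome. No biological explanation was tested against a group of samples.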
